A study of Mus musculus with 4 samples.

How the data were processed

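Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into open chromatin, in cultured mouse CD4 T cells. Per the labels, the cells came from 10-week-old C57BL/6 mice and were either CTCF-WT (carrying a tamoxifen-inducible Cre, CreER, with intact Ctcf) or CTCF-KO (CreER with loxP-flanked Ctcf alleles). The cells were stimulated through CD3ε and CD28 and kept for 6 days, with medium changed and IL-2 added at 100 U/ml every 2 days and 4-OH tamoxifen given on the first day alone. Libraries were made from 50000 nuclei. There were 4 libraries, 2 per genotype, here called WT replicates 1 and 2 and KO replicates 1 and 2. Groups and replicate numbers were taken from the sample titles.

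The data used were 4 peak lists, 1 per library, so peaks had been called in each sample and not on pooled samples. The submitters' processing notes name the mouse genome build mm10, Bowtie2 2.3.5.1, Picard 2.18.23, MACS2 2.2.7.1 and deepTools 3.5.1, without their settings, and whether reads were shifted for the transposase's offset is not given in the sources used here. Each deposited list gives, for every peak, its position and summit, a display score, the authors' fold enrichment over background (a linear ratio), and the authors' −log10 p-value and −log10 q-value. The smallest −log10 q in a deposited list was between 1.32 and 1.37, which matches a calling threshold of q = 0.05. The deposited peaks carry running numbers, and between 1.75% and 1.85% of the numbers were missing from each list, so some called peaks had been removed; the reason is not given in the sources used here. The shortest peak was 100 bp in each of the 4 lists. The fold, p and q of a peak are the authors' values. They were used to rank or filter peaks within their own list and to recover a measure of background. Summary values are also set side by side for the separately called lists.

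Peaks on the 19 autosomes and X were used, which is 20 chromosomes; between 3 and 4 peaks per list lay on Y. Peaks of the 4 lists that overlapped by at least 1 bp were merged into union regions. A region was WT-reproducible when both WT lists had a peak in it and KO-reproducible when both KO lists did. WT-only regions had a peak in both WT lists and in neither KO list, and KO-only regions the mirror image. The strength of a region was the within-list percentile of the −log10 p of its best peak, averaged over both lists of a genotype and divided into 10 deciles. Intervals on shares are 95% Wilson intervals; they cover counting error only and do not describe how cultures or animals vary. Peak lists hold no read totals, so sequencing depth is unknown. A relative measure was recovered by solving each peak's fold and p (peaks with −log10 p below 12) for the Poisson background λ, at a tolerance of 0.001 on the −log10 p; λ scales with the number of reads times the fragment length, and the fragment lengths are not given in the sources used here.

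Gene positions came from a RefSeq table of the same assembly as the files' build (49550 genes, 21627 of them protein-coding). The table gives no strand, so the planned distance to a transcription start site was replaced by the distance to the nearer of both gene ends, in the main tests and in the alternatives. No genome sequence was used here, so the planned tests of the CTCF motif and other motifs were not run. Gene-end shares were compared between exclusive regions and regions present in all 4 lists by a Mantel-Haenszel odds ratio stratified by strength decile (deciles drawn anew over the regions compared), with a two-sided Cochran-Mantel-Haenszel test. The p-values across regions compare these lists; regions are not replicates. For the number of peaks a two-sided exact permutation test was used, which with 2 against 2 libraries cannot give a p below 0.333.

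The lists of genes, the tests and most of the other settings were fixed before the data were examined. The 14 lists, with 222 entries that were all found in the gene table, were T cell identity and TCR signalling, activation and IL-2 response, Th1, Th2, Th17, Treg and inhibitory receptors, naive, memory and Tfh, cytotoxic, CD8 and NK markers, B cell markers, myeloid markers, CTCF and cohesin machinery, loci known for CTCF boundaries, p53, apoptosis and cell cycle, and housekeeping. For each list the regions within 50 kb of either end of a member were pooled, and the WT-only share of the WT-reproducible ones (or the KO-only share of the KO-reproducible ones) was set against 10000 random gene lists matched gene by gene on the number of such regions, with a two-sided permutation p and Benjamini-Hochberg adjustment over 28 tests. Named in the text were Ctcf, the 10 WT-only and 10 KO-only regions with the highest strength in the weaker of both lists (with the nearest protein-coding gene end within 100 kb), list genes with an exclusive region within 1 kb of an end, and up to 4 genes per list with the most exclusive regions, to about 30 names per direction; a few items that this rule selects are not reported here.

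The procedures were tested on simulated data. With 200 planted WT-only and 200 planted KO-only regions among the 88429 union regions, 200 and 200 were recovered and no others were called. Every other region was placed in all 4 lists with its edges slightly trimmed. This checks the assignment of classes only, as the loss of weak peaks near the calling threshold was not simulated. A planted odds ratio of 2 over 56000 simulated regions was estimated as 2.02. A list whose losses were planted at 2 times the usual share came out at 2.24 times (permutation p = 0.002, the smallest that the 1000 random lists of this simulation can give). With losses placed at random among the 59423 WT-reproducible regions, the first simulation gave 4 of 14 lists a p of 0.05 or less. Over 200 further simulations such a p arose in 5.21% of list tests (95% interval 4.45 to 6.10). In none of the 200 did a list pass after adjustment, but so few random lists were drawn that a list alone could not have passed. That count therefore does not measure the error of adjusted calls. Losses were placed independently of one another and gains were not simulated, so clustered losses and the KO-only tests are not covered. The list of CTCF-boundary loci reached a p of 0.05 or less in 12.0% (8.20 to 17.2). Its members are clustered and share regions, while the random lists are scattered, so p-values for that list are too small. An alternative was therefore added after this simulation, in which the losses or gains were shifted along the genome by a random number of regions and the list's own regions were kept.

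Other alternatives were stricter thresholds (−log10 q of at least 5 and of at least 10), lists cut to the length of the shortest, overlap of at least 50% of both peaks, summits within 250 bp, each library left out in turn, a block on the replicate number, a gene-end distance of 2500 bp, all annotated genes, no stratification, and gene lists by nearest gene end or within 10 kb. Added after the data were seen were gene-list tests adjusted for strength and without each list's top gene, besides the shift along the genome. Computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3; figures were drawn with matplotlib 3.10.9.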

Results

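Accessible chromatin was profiled in activated CD4 T cells with intact Ctcf (WT, 2 libraries) and after induced deletion of Ctcf (KO, 2 libraries). CTCF is the zinc-finger protein that binds insulator sites and, with cohesin, anchors chromatin loops; the series concerns a three-dimensional enhancer network that depends on it. The lists held 70875 and 67358 peaks in WT replicates 1 and 2 and 60756 and 57758 peaks in KO replicates 1 and 2, covering 14.5, 13.7, 13.6 and 12.6 Mb of the mm10 genome. The background λ implied by the authors' fold and p, the nearest available stand-in for depth, was 0.653 and 0.716 in the WT libraries and 0.651 and 0.809 in the KO libraries. The series calls the libraries biological replicates; nothing further in the labels says whether replicates came from separate animals, so the spread between them may be partly technical.

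At Ctcf itself (chromosome 8, 105636474 to 105682922), the peak calls differed between the genotypes inside the gene. The region over the gene end at 105636474 (105635963 to 105636574) had a peak in all 4 lists. The adjacent region 246 bp inside the gene (105636720 to 105637028) had a peak only in WT, at percentiles 82.5 and 87.3 of the WT lists. A region inside the gene at 105661255 to 105661447 was also WT-only, at percentiles 74.0 and 58.9. Just beyond the other gene end, a region over Carmil2, an actin-capping regulator used in CD28 costimulation (105685794 to 105686296), was present in all 4 lists. Peak calls do not measure the deletion, so these 2 WT-only regions are a difference between the lists at the targeted gene and no more than that.

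KO libraries had fewer called peaks than WT libraries. The mean was 59257 ± 2120 (SD, n = 2) in KO and 69116.5 ± 2487 (SD, n = 2) in WT, a ratio of 0.857, and both KO lists were shorter than both WT lists. The two-sided exact permutation p was 0.333, the smallest that 2 against 2 libraries allow. Lists of one genotype resembled each other more than lists of different genotypes. The share of peaks overlapped by the other list, averaged over both directions, was 88.6% between the KO lists and 87.7% between the WT lists, against 73.8% to 75.8% for the 4 pairs across genotypes. The Jaccard index of covered bases was 0.753 and 0.742 within genotypes and 0.583 to 0.603 across them.

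The 4 lists merged into 88429 regions, and many more were exclusive to WT than to KO. Of 59423 WT-reproducible regions, 14007 had no KO peak (23.6%, 95% interval 23.2 to 23.9). Of 51515 KO-reproducible regions, 4819 had no WT peak (9.35%, 9.11 to 9.61), and 42279 regions had a peak in all 4 lists. Dividing the libraries by genotype gave 18826 exclusive regions, and the other 2 ways of dividing them into pairs gave 1575 and 1255. The excess of WT-only regions depended in part on list length. With all lists cut to 57758 peaks the counts were 11052 WT-only and 8101 KO-only. With 1 library left out both counts rose, to 15868 WT-only and 7558 KO-only without KO replicate 1, 15352 and 9642 without KO replicate 2, 18135 and 7820 without WT replicate 1, and 19579 and 6275 without WT replicate 2.

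**Figure D1:**
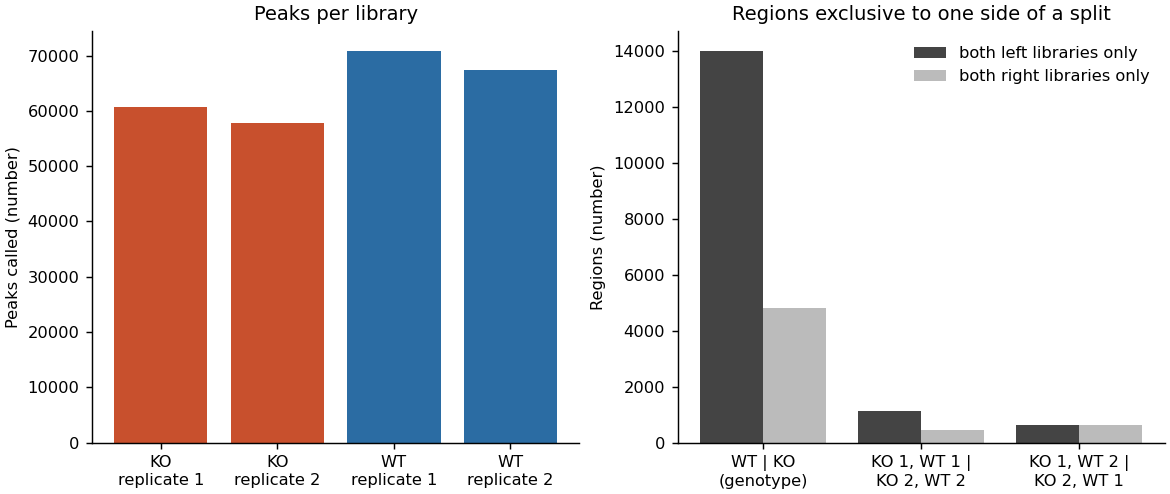
Left, number of called peaks per library (bars; KO in red, WT in blue); both KO lists, at 60756 and 57758 peaks, are shorter than the WT lists, at 70875 and 67358. Right, number of regions with a peak in both libraries of one side and neither of the other, for the 3 ways of dividing 4 libraries into pairs; the division by genotype gives 14007 and 4819 regions, and the others at most 1118 on a side.

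Peaks absent from KO reached well into the stronger WT peaks, whereas peaks gained in KO were nearly all weak. In the weakest decile of WT strength 37.6% of regions had no KO peak, in the sixth decile 29.0%, and in the strongest 1.04%. The mirror share of KO-reproducible regions without a WT peak started at 39.5% and was 2.19% in the sixth decile and 0.0194% in the strongest. Over the upper 5 deciles together the shares were 14.1% (13.7 to 14.5) for WT and 0.644% (0.554 to 0.750) for KO. With lists of equal length they were 11.6% (11.2 to 11.97) and 1.002% (0.887 to 1.13).

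**Figure D2:**
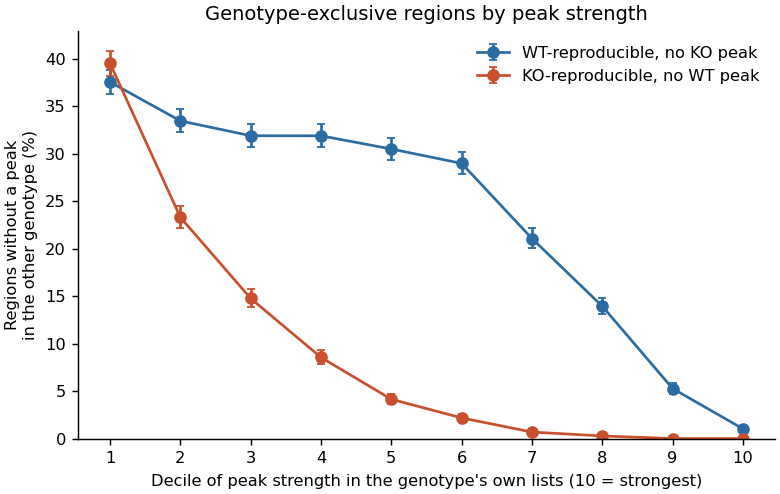
Share of a genotype's reproducible regions (%, y axis) that had no peak in either library of the other genotype, by decile of peak strength in its own lists (x axis; 10 is the strongest); points are shares and bars 95% Wilson intervals. The WT curve stays at 29.0% in the sixth decile where the KO curve is at 2.19%, and both end near 0 in the strongest decile, at 1.04% and 0.0194%.

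The WT-only region with the highest strength lay on chromosome 1 (135753034 to 135753249), 805 bp from an end of Csrp1, which encodes a LIM-domain protein of the actin cytoskeleton. It stood at percentiles 99.8 and 100.0 of the WT lists, with authors' folds of 52.4 and 59.0. Of the 10 strongest WT-only regions, 5 lay on variable-gene segments of the immunoglobulin heavy-chain locus on chromosome 12, which B cells rearrange to make antibodies: Ighv1-82 (115952379 to 115952651), Ighv1-74, Ighv1-61, Ighv1-70 and Ighv1-62-1, all at percentile 96.5 or above. Others lay 1995 bp from Dgat2, an enzyme of triglyceride synthesis (chromosome 7), 4997 bp from Zfp692 (chromosome 11), and inside Gcat, 2670 bp from Galr3 (chromosome 15). Between the ends of the Igh variable-gene interval (chromosome 12, 113572929 to 116009954, 183 annotated segments), 82 of 129 WT-reproducible regions had no KO peak (63.6%, 55.0 to 71.4), where 24.3 would follow from their strength, and 41 regions had a peak in all 4 lists. Of the 74 WT-reproducible regions on an annotated segment 33 were WT-only. That share is below that of the whole interval, so the losses were more frequent between segments than on them. In the variable-gene intervals of the T cell receptor loci the WT-only shares were 10 of 44 (Tcra and Tcrd), 10 of 41 (Tcrb) and 1 of 8 (Tcrg), and in that of Igk 1 of 3.

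The strongest KO-only region also lay in the Igh interval (114134451 to 114134847), at percentiles 91.1 and 92.1 of the KO lists. The others of the first 10 ranked between percentiles 75.4 and 85.3. They included regions inside Zbtb16 (chromosome 9, 48804635 to 48804827), which encodes the transcription factor PLZF of innate-like T cells, inside Rbm45 (chromosome 2), Samd9l (chromosome 6) and Ppcdc (chromosome 9, 366 bp from a gene end), and within 100 kb of Vit, Sval1 and Diras2. One, on chromosome 13 (75366877 to 75367414), had no protein-coding gene end within 100 kb.

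**Figure D3:**
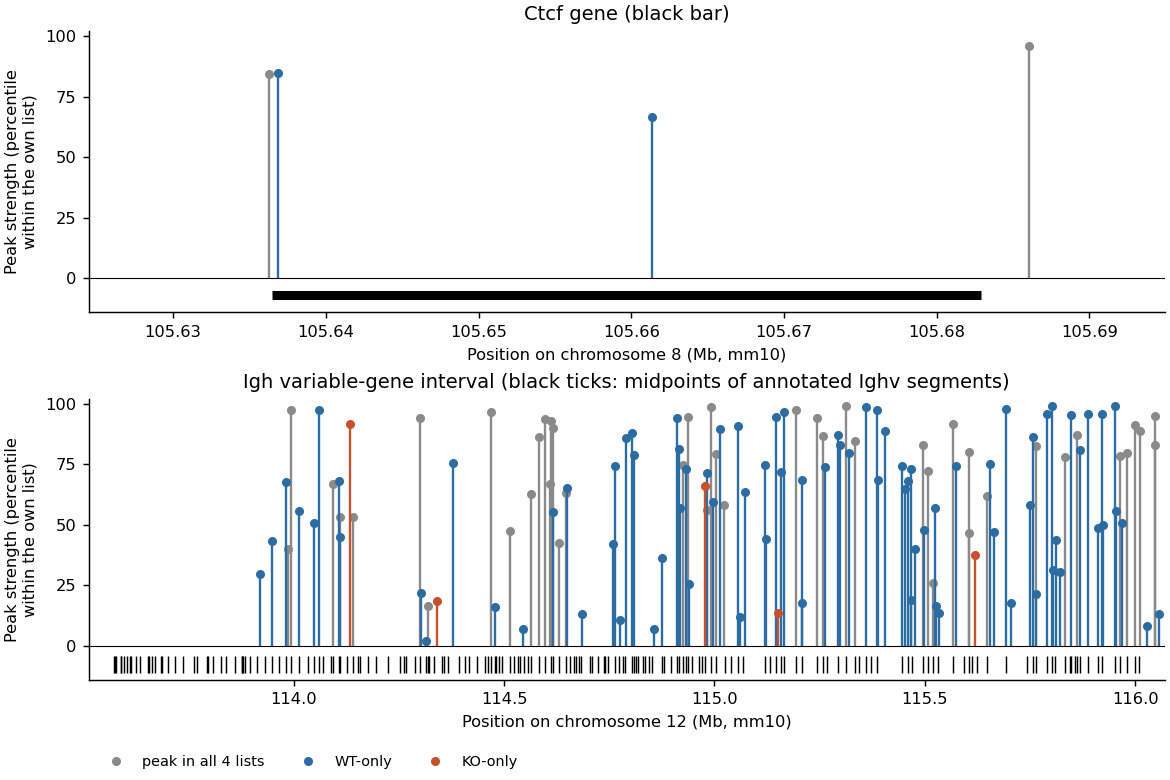
Regions at Ctcf (top; black bar, the gene) and across the Igh variable-gene interval (bottom; black ticks, annotated Ighv segments), placed by mm10 position in Mb (x axis). The height is strength as a percentile within the genotype's own lists (y axis; KO lists for KO-only regions, WT lists otherwise), and regions in 2 or 3 lists of mixed genotype or in 1 list are not drawn. Ctcf has 2 WT-only regions inside the gene, and in the Igh interval 82 WT-only regions are interspersed with 41 present in all 4 lists.

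Exclusive regions lay at gene ends less often than shared regions. A protein-coding gene end lay within 1 kb of 12.8% of WT-only regions, 13.9% of KO-only regions and 31.8% of regions present in all 4 lists. At equal strength the odds ratio against the latter was 0.462 (95% interval 0.436 to 0.489) for WT-only and 0.654 (0.594 to 0.719) for KO-only regions, both below 1 by the Cochran-Mantel-Haenszel test across regions. The contrast was wide among strong regions. With deciles drawn over WT-only and shared regions alone, 9.26% of 54 WT-only regions and 57.4% of regions present in all 4 lists in the strongest decile lay at a gene end. Regions outside genes made up 40.7% of WT-only, 38.1% of KO-only and 27.8% of shared regions. Among regions over 1 kb from gene ends, the odds ratio of lying inside a gene was 0.788 (0.754 to 0.824) for WT-only and 0.869 (0.806 to 0.937) for KO-only regions.

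Genes of T cell identity and TCR signalling kept their peaks more often than random genes. Of 403 WT-reproducible regions within 50 kb of these 23 genes, 62 were WT-only (15.4%, against a median of 22.1% in random lists; permutation p adjusted by Benjamini-Hochberg = 0.0196, and 0.028 with losses shifted along the genome). None of 20 regions near Satb1, a chromatin organiser of T cells, and none of 11 near Gata3, the regulator of Th2 cells, was WT-only; both genes were chosen after their values were seen. The members with the most WT-only regions were Cd247, with 7 of 27, and Cd3e, with 6 of 19, which encode chains of the T cell receptor complex, followed by Cd3d (5 of 14), Cd3g (5 of 15), Zbtb7b (5 of 18) and Lck (5 of 20). Cd3e, Cd3d and Cd3g are neighbours, so their counts share regions. At gene ends, WT-only regions lay by Cd3e (2), Zbtb7b (2) and Cd247, among others. The call was lost without KO replicate 1 (adjusted permutation p = 0.114) and within 10 kb (0.533). The difference from random lists was -6.75 percentage points in the main test, -5.43 without KO replicate 1 and -3.65 within 10 kb.

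Near Th2 genes, which include the Il4, Il5 and Il13 cytokine cluster, 25 of 159 regions were WT-only (15.7% against 23.7%, adjusted permutation p = 0.0378). With losses shifted along the genome the adjusted p was 0.212, and it was 0.134 without KO replicate 1, 0.165 without KO replicate 2, 0.0994 at −log10 q of at least 5 and 0.3 within 10 kb. The difference from random lists was -8.01 percentage points in the main test and stayed similar in size, at -7.55 with the shift, -7.36 without KO replicate 1 and -6.89 without KO replicate 2. Near Stat6, which transmits the IL-4 signal, 4 of 13 were WT-only, and near Il4 3 of 12. Near loci known for CTCF boundaries the share was higher, at 29 of 72 regions (40.3% against 26.7%, adjusted permutation p = 0.0205). This p is too small for clustered genes; with losses shifted along the genome it was 0.0784, adjusted for strength 0.189, without Kcnq1 0.134 and within 10 kb 0.179. The excess over random lists was 13.6 percentage points in the main test, 16.7 with the shift and 19.7 within 10 kb, but 8.31 adjusted for strength and 10.3 without Kcnq1. By nearest gene end it was 13.1 points (adjusted permutation p = 0.1996). In the Hoxa cluster, whose genes pattern the body axis, 4 of 6 regions near Hoxa9 and 4 of 6 near Hoxa10 were WT-only, including 1 within 1 kb of an end of Hoxa10. The shares were 6 of 9 near the imprinted gene Kcnq1 and 5 of 10 near the protocadherin gene Pcdhgc3.

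KO-only regions were frequent near genes of the Th17 programme, the helper T cells that make IL-17. Of 75 KO-reproducible regions near its 11 genes 17 were KO-only (22.7% against 7.69% in random lists, adjusted permutation p = 0.0056; the unadjusted 0.0002 is the smallest that the random lists can give). Each of the 11 genes had at least 1, with the neighbours Il17a and Il17f sharing theirs, and none lay within 1 kb of a gene end. The counts were 4 of 8 near Il1r1, the IL-1 receptor, 3 of 14 near Stat3, 2 of 6 near Ahr and 2 of 14 near Il23r, at strengths up to percentile 44.4 of the KO lists. The strongest KO-only region stood at percentile 37.9 near Stat3 and 30.1 near Il1r1, but at 4.88 near Il17a and Il17f and 5.24 near Ccr6. With gains shifted along the genome the adjusted p was 0.0784, and within 10 kb it was 0.369. The excess over random lists was 14.97 percentage points in the main test, 13.3 with the shift and 13.0 within 10 kb. It was 11.7 without Il1r1 and 10.6 adjusted for strength. The WT-only share near Th17 genes, 13 of 66 regions, did not pass (19.7% against 26.1%, adjusted permutation p = 0.569).

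In the main test none of the other 24 list comparisons passed an adjusted p of 0.05. Near activation and IL-2 response genes 69 of 379 regions were WT-only (18.2%, against 22.7% in random lists, adjusted permutation p = 0.192) and 28 of 344 KO-only (8.14%, 0.95). The WT-only share passed as lower without WT replicate 1 (adjusted permutation p = 0.0291), without WT replicate 2 (0.0383) and by nearest gene end (0.0243). Junb had 7 of 24 WT-only and Nr4a1, an immediate-early gene of receptor stimulation, 6 of 17. At gene ends, WT-only regions lay by Irf4, Nfatc1 and Junb and KO-only regions by Il2ra, Cd69, Cish and Socs1. Near Th1 genes 45 of 189 regions were WT-only (23.8%, 0.985) and 11 of 157 KO-only (7.01%, 0.935). Both WT-only regions at an end of Eomes, which encodes a T-box factor, were without a shared region beside them, and Ifng and Hlx each had 1 WT-only region at an end. Th2 genes had 15 of 149 KO-only regions (10.1%, 0.631), with 2 at the ends of Il13 and 1 each at an end of Stat6 and Irf1, and Stat6 also had a WT-only region at an end. T cell identity genes had 27 of 371 (7.28%, 0.935) and loci known for CTCF boundaries 2 of 45 (4.44%, 0.631).

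Near Treg and inhibitory receptor genes 35 of 183 regions were WT-only (19.1%, adjusted permutation p = 0.569) and 11 of 166 KO-only (6.63%, 0.935), with WT-only regions at the ends of Icos, Lrrc32 and Nrp1. For naive, memory and Tfh genes the counts were 46 of 253 (18.2%, 0.438) and 22 of 237 (9.28%, 0.828), with WT-only regions at the ends of S1pr1 and Lef1 and a KO-only region at an end of Bach2. For CTCF and cohesin machinery they were 37 of 150 (24.7%, 1.0) and 11 of 129 (8.53%, 0.935), for p53, apoptosis and cell cycle genes 54 of 259 (20.8%, 0.743) and 12 of 220 (5.45%, 0.569), and for housekeeping genes 34 of 148 (22.97%, 0.935) and 6 of 122 (4.92%, 0.587).

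Markers of cells that such a culture could also hold did not pass the main test either. Cytotoxic, CD8 and NK markers had 26 of 106 WT-only (24.5%, adjusted permutation p = 0.95) and 6 of 86 KO-only regions (6.98%, 0.935). Myeloid markers had 21 of 86 (24.4%, 0.935) and 9 of 71 (12.7%, 0.566). B cell markers had 23 of 80 (28.8%, 0.935) and 12 of 72 (16.7% against 7.46% in random lists, 0.169). The KO-only share near B cell markers passed as higher without WT replicate 2 (23.6% against 10.3%, adjusted permutation p = 0.0325).

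**Figure D4:**
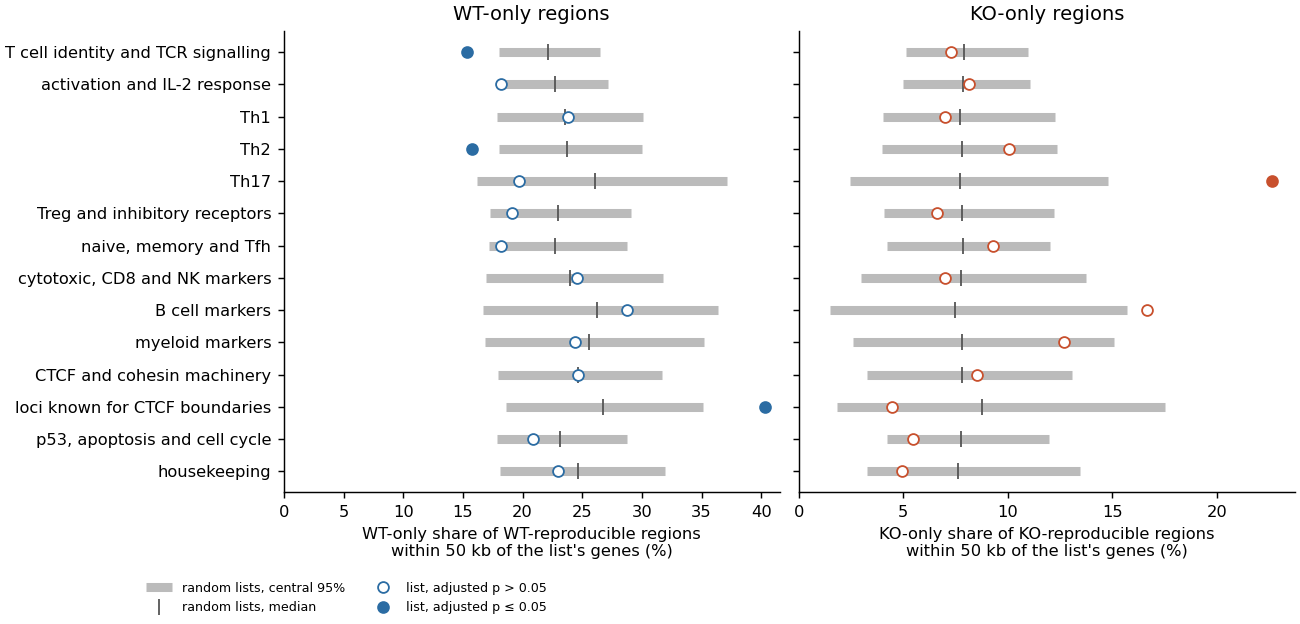
Share of WT-reproducible regions that were WT-only (left, %) and of KO-reproducible regions that were KO-only (right, %) within 50 kb of the genes of 14 lists (rows). Circles are the lists, filled at an adjusted permutation p of 0.05 or less, grey bars the central 95% of 10000 random lists and ticks their median. T cell identity (15.4%) and Th2 (15.7%) lie below their bars and CTCF-boundary loci (40.3%) above on the left, and Th17 (22.7%) lies above on the right; of these 4, T cell identity alone also passed with losses or gains shifted along the genome.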

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

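In all, 13 results were recomputed under 121 result-by-setting alternatives, of which 88 were kept, 18 moved and 15 were weaker. Kept meant the same side of the threshold for a test and within the spread for a value. For a count it meant within a fixed ratio of the main count. That ratio was wide, as 20472 WT-only regions counted as kept against 14007 in the main setting. No test or value changed direction, and counts have no direction to change. The strength-adjusted test, the test without each list's top gene and the shift along the genome were chosen after seeing the data. Motif tests were not run, as no genome sequence was used here. The number of reads is unknown, and a region counted as absent had no call at q = 0.05, which is not the same as closed chromatin.

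With lists of equal length the KO-only count was 8101, the loss over the upper 5 deciles of strength 11.6% and the excess of within-genotype overlap 16.0 percentage points (13.3 as deposited). At −log10 q of at least 10 the upper-decile loss was 12.2%, and with overlap of at least 50% of both peaks the overlap excess was 14.7 points. The cause of these shifts was not tested. Leaving out 1 library, which loosens what counts as reproducible or absent, gave 6275 to 9642 KO-only regions, an upper-decile loss of 14.7% to 16.5% and 2 to 6 passing gene-list tests.

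The 4 gene-list calls became 0 within 10 kb and 1, T cell identity, with the shift along the genome. Over all list tests, an unadjusted permutation p of 0.05 or less was reached by 4 within 10 kb and 5 with the shift. Within 10 kb, CTCF-boundary loci (unadjusted permutation p = 0.0064) were the only main call among them. The others were at 0.267 (T cell identity), 0.103 (Th2) and 0.145 (Th17). With the shift, all 4 main calls were among the 5. The Th2 call was lost under 6 settings, with adjusted p of 0.0994 at −log10 q of at least 5 and 0.2 by nearest gene end. The CTCF-boundary call was lost under 5 and the Th17 call under 2.

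Replicate numbers are shared by the genotypes, but the labels tie them to no common animal or day, and the differences between replicates 1 and 2 correlated at r = 0.109 across 42279 regions, which are not independent. With the replicate number as a block the KO minus WT difference in peaks was -9859.5 (exact sign-flip p = 0.5, the smallest possible). Within number 1 the block gave 21459 WT-only and 11672 KO-only regions, and within number 2 20472 WT-only and 11053 KO-only regions, more because 1 list per genotype then decides.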

Other observations

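The tests along the genome, those of the excess of WT-only regions, of deletion or divergence at Igh, of peak width and of clustered gains were chosen after the result was seen.

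The density of losses and gains differed along the genome. The WT-only share per chromosome ranged from 18.9% on X to 25.1% on chromosome 7. Among 1283 windows of 1 Mb, the WT-only share was higher than that of the genome in 2, both in the Igh interval (51 of 75 regions and 28 of 49), and lower in 1, on chromosome 17 from 71 Mb, where 0 of 37 regions were WT-only (exact binomial test, adjusted p = 0.0466; the window holds Lpin2 and Smchd1). KO-only regions were dense in 11 of 1217 windows. The first was on chromosome 15 from 74 Mb, with 14 of 36 regions (exact binomial test, adjusted p = 0.00188), a window with genes of the Ly6 family such as Ly6d. Others were on chromosome 10 from 18 Mb (15 of 42), chromosome 18 from 79 Mb around Setbp1 (13 of 36) and chromosome 9 from 48 Mb around Zbtb16 (13 of 40). All window tests treated regions as independent and took no account of peak strength, with which exclusive shares fall. A window rich in weak peaks could therefore be called dense.

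Exclusive peaks were narrow. In the WT lists the median width was 141 bp in WT-only regions and 213.5 bp in regions present in all 4 lists. WT-only regions were narrower in 10 of 10 deciles of strength, which argues against peak strength as their whole cause. In the KO lists the median was 140 bp in KO-only regions, against 192 and 189 bp over all peaks of KO replicates 1 and 2. KO-only widths were not compared by strength. Gains were not found beside losses more often than shared regions were. A WT-only region lay within 10 kb of 27.0% of KO-only regions and 30.04% of regions present in all 4 lists, an odds ratio of 0.93 at equal strength (95% interval 0.861 to 1.004), which shows no excess of accessibility gained next to lost regions.

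WT-only regions outnumbered KO-only regions. Lower depth of the KO libraries stays open: the KO to WT ratio of background λ was 1.07, but λ also scales with fragment length, which is unknown. Weak enrichment in KO that costs weak peaks alone is argued against by the losses by WT strength. These were 37.6% in the weakest decile, 29.0% in the sixth and 1.04% in the strongest. Over the upper 5 deciles together the loss was 14.1%, and 11.6% with lists of equal length. Lower sensitivity as part of the cause stays open. It would by itself leave WT regions without a KO peak and few strong KO-only regions (0.644%). List length adds to the excess. The authors' values within the lists run the other way or are alike. The median fold was 12.15 and 12.16 in KO and 12.02 and 12.24 in WT. The largest −log10 q was 381 and 402 in KO and 347 and 338 in WT. Values from separately called lists do not exclude lower sensitivity in KO. With 3 ways of dividing the libraries a share under 0.05 cannot be reached; 1 of the 3, the real one, gave as many exclusive regions, with 18826 against at most 1575 in the others. Loss of accessibility at CTCF-dependent distal sites remains a candidate explanation that these lists could not address without motifs or binding data.

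WT-only regions were dense in the Igh variable-gene interval. A property of all antigen receptor intervals is argued against by the others with at least 10 regions, where 23.5% (20 of 85) were WT-only, and B cells in the WT cultures by 0 of 12 B cell markers with a WT-only region above the 50th percentile at a gene end. A deletion of the whole interval is argued against by regions present in all 4 lists in 17 of the 19 windows of 100 kb that hold at least 3 WT-reproducible regions. Deleted or strain-diverged stretches within it stay open and cannot be told apart from an effect of CTCF loss, since the longest run of regions without a KO peak was 13, against a median of 9 in random orders (permutation p = 0.0855). Strong regions were lost too: 23 of 46 Igh regions above the 80th percentile were WT-only, against 4.01% genome-wide.

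KO-only regions were frequent near Th17 genes. A single gene's neighbourhood is argued against by the permutation p without Il1r1, 0.0042 before and 0.0392 after adjustment over all lists. Weaker peaks near these genes as the whole cause are argued against by the strength-adjusted permutation p, 0.0020 before and 0.0187 after that adjustment. The excess over random lists fell from 14.97 percentage points in the main test to 10.6 when adjusted for strength, so strength may account for part. Both tests used random lists of scattered genes, which do not address clustered gains. Clustering of gains along the genome stays open. With gains shifted the excess over the random median was 13.3 percentage points, against 14.97 in the main test, and the permutation p was 0.0084 before and 0.0784 after adjustment over all lists, so the lost call does not show that clustering accounts for the excess.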
